A study of Mus musculus with 44 samples.

How the data were processed

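Total RNA of the hippocampus of 44 C57BL/6J mice, extracted with phenol and chloroform, was sequenced on BGI-500 instruments, 1 library per mouse. The labels give age (5, 15 or 18 months) and a diet label (CD or MR) for each library, and the descriptions of the libraries name 1 of 4 lanes. The labels do not give the sex of the mice. The values are FPKM as deposited by the authors, in 1 table of 13218 loci. No further scaling between libraries is named. Per the submitters' processing notes, reads were handled with Trimmomatic 0.38, HISAT2 (version not given) and StringTie 1.3.4d on the mouse genome build GRCm38.p6. How the loci were chosen and which annotation was used are not stated. The loci carry numbers that StringTie gives to merged assembled transcripts. Of them 8941 have 1 gene symbol, 853 several, 3187 none, and 219 have 1 gene symbol together with the name of a small RNA. In 18 a date stands in place of a symbol, as spreadsheets make of some gene names, and 232 symbols stand on more than 1 locus. A locus with several symbols is written with a slash and is not assigned to a single gene. A symbol with several loci is given as uncertain. FPKM hold no read counts, and no steps of whole reads were found among the low values, so the depth of each library is unknown and no counting interval is given.

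Loci with at least 1 FPKM in at least 6 of the 44 libraries were kept (13009; 209 were left out), and log2(FPKM + 1) was fitted in limma 3.58.1 (R 4.3.3) with 1 mean for each of the 6 groups, 38 residual degrees of freedom and an intensity trend in the prior variance. The comparisons were MR against CD at each age and averaged over the 3 ages, each pair of ages within CD and within MR, and the interaction of MR with age (11 in all). P values are 2-sided and adjusted by Benjamini-Hochberg over the loci of a comparison, with 0.05 as the threshold. The model, the filter, the 37 gene lists and the rule for naming genes were chosen before the data were examined.

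The rule names, for MR against CD and for 15 or 18 against 5 months in CD, up to 10 higher and 10 lower genes with the smallest adjusted p under 0.05, for other comparisons up to 5 and 5, for the interaction 6, and where none passes the 5 with the smallest p. Genes with only a clone or predicted name are passed over, and some results that the rule would name are not reported here. From each list called, or with a member past the test, up to 4 members with the smallest p may be named, with the FGF21 receptors in each MR comparison and any member that serves as an example. The genes shown in the plot of FPKM by group were picked from the named genes after their values were seen.

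Gene lists held pathways, complexes and markers of the cell types and neighbouring tissues that a hippocampal sample could hold. The list of oligodendrocyte precursors and newly formed oligodendrocytes, with 8 of 14 members tested, is called precursors for short. It holds genes of the whole oligodendrocyte lineage, such as Olig2, so it does not separate precursors from mature cells. They were matched by symbol to loci with 1 gene symbol, with or without the name of a small RNA. The 30 lists with at least 5 genes tested were compared with all other loci by camera of limma with the preset correlation between genes of 0.01, and again with a correlation estimated for each list; P values were adjusted over the lists of a comparison. For each list the members past the test were counted over all genes tested and adjusted over the list alone. A score per library, the mean of the centred log2(FPKM + 1) values of a list, was compared between groups by 2-sided exact permutation tests (Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1). This was planned for the cell type markers in 5 comparisons, in 70 tests, and was extended to all 30 lists and 9 comparisons after the data were seen, because genes of a list can vary together by more than the preset correlation. The 3 list tests ask different questions and gave different calls. Where they differ the adjusted p of the others is given, for several lists together as a range, except that no exact test was run on the average over ages. Shares of loci without a symbol and of mitochondrial rRNA loci, loci at 0 and Ttr were compared the same way, adjusted over the 9 comparisons of a measure. Positions are those of GENCODE M21 on GRCm38, and figures were drawn with matplotlib 3.10.9.

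The alternatives chosen beforehand and run were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, a fit of only the groups compared, lane as a factor, the number in the sample names as a block, array weights, an estimated correlation, the median in place of the mean in marker scores, shared control libraries divided between the 2 differences, and leaving out each library in turn. A covariate of sex-linked transcripts was planned if the libraries differed clearly and was not run. Of its list 1 transcript was tested, Eif2s3y of the Y chromosome, at 1.91 to 12.4 FPKM over all libraries. By that 1 transcript the mice were likely all male. Others were added after the data were seen. They were the share of loci without a symbol as a covariate, only loci with a symbol, leaving out the 6 libraries with over 8% in loci without a symbol, Ttr as a covariate, removal of each library's trend with transcript length and GC content over 8756 loci, only the lane that holds both groups, and merged loci in the lists. Also added were list tests of the differences between ages, simulated libraries for the age comparison and its ranking on divided libraries, the exact test of all lists, and leaving out libraries in the list tests. For each comparison 100 splits of the libraries into groups of the same sizes were counted. The procedure was tested on simulated data with 200 changed loci: in the comparisons of 2 groups it recovered between 20.9% and 38.8% of those changed by a factor of 1.5, between 52.2% and 76.1% at a factor of 2 and between 87.9% and 97% at a factor of 4. For the interaction it recovered 8.96%, 32.8% and 83.3%, and there were 2 to 8 false calls. Most changes of a factor of 1.5 would thus be missed. The simulated loci varied independently, while loci of the real libraries can vary together. For MR versus CD at 18 months a random split of the real libraries called 4751 loci. The simulated number of false calls may therefore be too low for these data.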

Results

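RNA of the mouse hippocampus, the part of the brain that lays down new memories, was sequenced in 44 libraries from C57BL/6J mice of 5, 15 and 18 months, each from 1 of 2 diet labels, CD and MR. MR is read here as the methionine restriction that the series title names, a diet low in the essential amino acid methionine, and CD as its control diet. The groups held 6 libraries of 5M-CD, 7 of 5M-MR, 8 of 15M-CD, 8 of 15M-MR, 8 of 18M-CD and 7 of 18M-MR. Values are FPKM of assembled loci, of which 13009 were tested. Read counts, and with them the depth of each library and its counting error, are unknown. The FPKM of a library summed to between 213116 and 282327, and between 485 and 967 of its loci were at 0. Differences below are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM, with the standard error (SE) of the limma fit. Directions across libraries count those of the first group that lie beyond the mean of the second.

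Signs of neighbouring tissue and of RNA quality varied between libraries. Ttr, the transthyretin gene of the choroid plexus, ranged from 7.72 to 4910 FPKM and differed between no groups tested (smallest adjusted p = 0.86, exact permutation tests). Loci without a gene symbol held between 3.3% and 12% of a library's FPKM sum, and the mitochondrial rRNA loci between 2.93% and 12.5%. Under MR the share of loci without a symbol was 4.2% ± 0.617 (SD, n = 7) at 5 months, 6.23% ± 1.21 (n = 8) at 15 months and 7.43% ± 2.83 (n = 7) at 18 months. It was higher than at 5 months by 2.03 percentage points at 15 months (2-sided exact permutation p = 0.00124, adjusted p = 0.0112) and by 3.23 at 18 months (exact permutation p = 0.00699, adjusted p = 0.0315). In CD it was 5.46% ± 1.21 (n = 6), 5.9% ± 1.48 (n = 8) and 6.41% ± 1.65 (n = 8) at the 3 ages, with no difference past the test. The mitochondrial rRNA share moved the same way under MR, by 2.65 points at 15 months (exact permutation, adjusted p = 0.00839) and 3.71 at 18 months (adjusted p = 0.042). So did the number of loci at 0, in MR higher than at 5 months by 156 at 15 months (exact permutation, adjusted p = 0.0042) and by 211 at 18 months (adjusted p = 0.00525). In 6 libraries the share without a symbol was over 8%: 15M-CD 7, 15M-MR 5, 18M-CD 8 and 18M-MR 1, 2 and 7. The sequencing lanes follow the groups closely. All of 15M-MR lay on lane 4 and 15M-CD had 5 libraries on lane 3 and 3 on lane 4. At 18 months, 18M-CD had 7 on lane 2 and 1 on lane 3, and 18M-MR 6 on lane 3 and 1 on lane 1. Of the 5-month libraries, 5M-CD had 5 on lane 1 and 1 on lane 4, and 5M-MR 2 on lane 1 and 5 on lane 2.

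**Figure D1:**
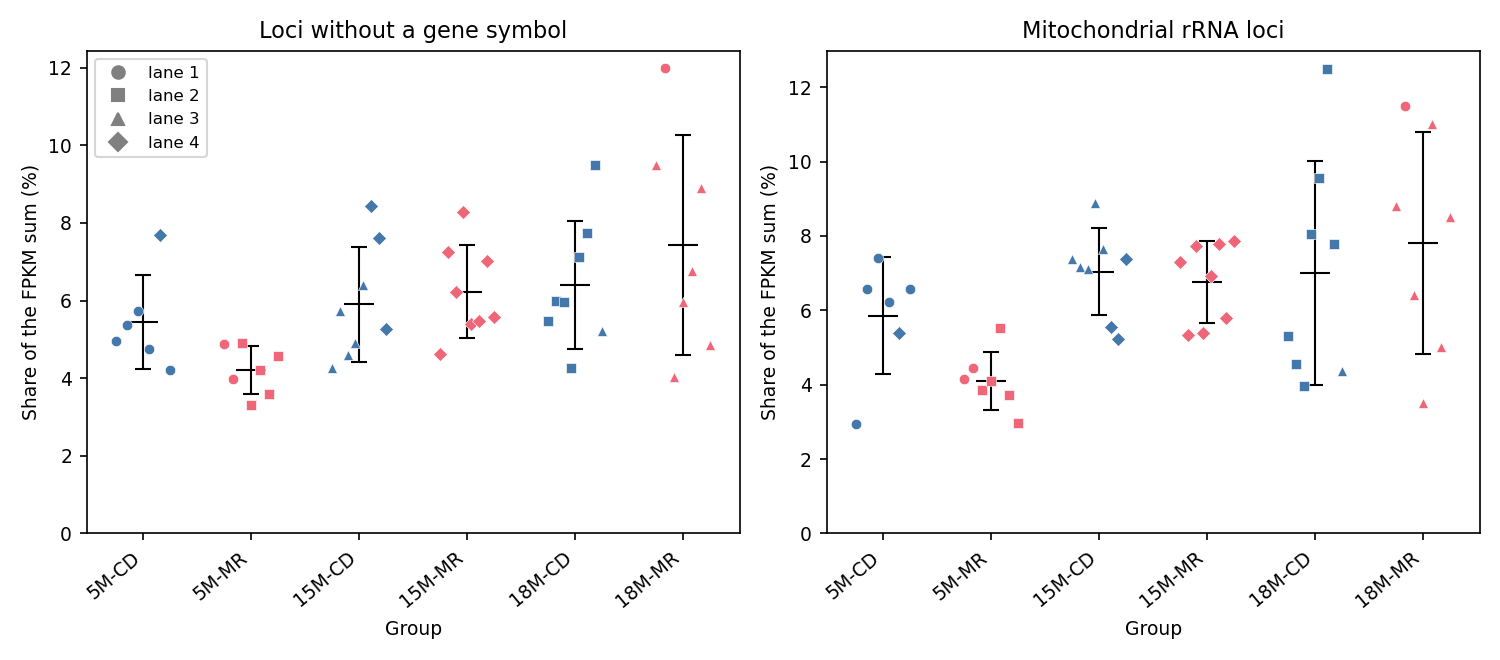
Share of each library's FPKM sum (%, y axis) in loci without a gene symbol (left) and in the mitochondrial rRNA loci (right), by group (x axis). Points are libraries, blue for CD and red for MR, with the marker giving the lane; black lines are the mean and SD of the group; the share without a symbol reached 12% in 1 library of 18M-MR.

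The comparison of 15 with 5 months in CD asks what changed in the hippocampus by middle age on the control diet. The activity genes were lower at 15 months. Fos, an immediate early gene that neurons switch on when they are active, was at 8.09 ± 2.04 FPKM (SD, n = 6) in 5M-CD and 3.69 ± 0.725 (n = 8) in 15M-CD, a difference of −0.94 (SE 0.151, adjusted p = 0.000315). Ier2 (−0.69, SE 0.131, adjusted p = 0.00362), Nr4a1 (−0.88, SE 0.195, adjusted p = 0.0207) and Arc, which acts at synapses during memory formation (−1.03, SE 0.233, adjusted p = 0.0259), fell with it. Rbm3, a cold-inducible RNA-binding protein gene (−0.89, SE 0.187, adjusted p = 0.0128), and the merged locus of 1600002K03Rik/Cirbp, not assignable to either gene (−0.69, SE 0.139, adjusted p = 0.00777), fell too. Cort, a neuropeptide of interneurons related to somatostatin, differed by −0.98 (SE 0.205, adjusted p = 0.0127). Olfml3, a gene of microglia, rose from 5.12 ± 0.313 to 8.95 ± 1.49 FPKM (0.69, SE 0.133, adjusted p = 0.00472). Also higher were Gabra2, a subunit of the GABA-A receptor (1.36, SE 0.29, adjusted p = 0.0137), and the merged locus of Serpina3g/Serpina3n, which holds a marker of reactive astrocytes (0.84, SE 0.184, adjusted p = 0.0178). Gabra2 peaked at 15 months, so its rise was not steady with age. Its means at 5, 15 and 18 months were 5.04, 14.9 and 8.54 FPKM in CD and 5.12, 15.8 and 8.01 under MR. Whether the 15-month mice differ in more than age, raised below for other loci, was not tested for Gabra2.

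In all, 10 loci rose and 28 fell between 5 and 15 months in CD at an adjusted p under 0.05, of which 3 and 12 have no symbol, and 1070 loci had an unadjusted p under 0.05. A set of 10 loci near 0 in every 15-month library, described below, may be among those that fell. How many of these calls they make up was not counted, so the counts need not be an effect of age alone. With 1 library left out there were 28 to 44 loci for 15 versus 5 months in CD, and array weights gave 230. For the genes named above each difference was seen in 8 of 8 libraries of 15M-CD. The other named calls were Lztfl1 (1.14), Snhg12 (0.34), Nin (−1.72), the merged loci of Tmem254b/Tmem254c (−1.35) and Entpd4/Gm21685 (−0.76), and Tubb5 (−2.29, adjusted p = 3.43e-05), which is uncertain because 3 loci carry that symbol. Of the 16 named calls, 8 held whichever library was left out: Olfml3, Tubb5, Tmem254b/Tmem254c, Fos, Ier2, Entpd4/Gm21685, 1600002K03Rik/Cirbp and Rbm3. Gabra2 was lost without 5M-CD 8, Cort, Nin and Serpina3g/Serpina3n without 5M-CD 6 or 8, and Lztfl1 without 5M-CD 2, 9 or 10. Nr4a1 was lost without 5M-CD 2, 4, 8 or 9 or 15M-CD 4 or 9, Arc without 5M-CD 2, 4, 8 or 9 or 15M-CD 4, 7 or 8, and Snhg12 without any of 10 libraries.

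As gene lists fixed before the data were examined, the immediate early genes showed the clearest difference. Of 14 tested members 4 fell over all genes tested and 8 adjusted over the list alone, with a mean of −0.48 (camera adjusted p = 1.42e-12; adjusted p = 0.0062 with an estimated correlation). Their score per library, the mean of the centred values, was 0.382 ± 0.116 (SD, n = 6) in 5M-CD and −0.102 ± 0.156 (n = 8) in 15M-CD, lower in 8 of 8 libraries (2-sided exact permutation p = 0.000333, adjusted p = 0.00999 over 30 lists). Lower too by the exact permutation test, each in 8 of 8 libraries, were the glucocorticoid-induced genes (mean −0.25; 0 members past the test, 2 lower adjusted over the list alone) and the targets of ATF4, the transcription factor of the amino acid response (mean −0.24; 3 lower adjusted over the list alone), both at an adjusted p of 0.0466. Camera called both (adjusted p = 0.0054 and 0.000873), each with an adjusted p = 0.245 with an estimated correlation. Of the ATF4 targets the amino acid transporter Slc7a5 differed by −1.69 (adjusted p = 0.203) and Slc7a1 by −0.48, neither past the test. Camera with the preset correlation called 9 further lists, none of them with an estimated correlation. Higher were ribosomal proteins (68 genes, mean 0.21, adjusted p = 1.73e-10; adjusted p = 0.566 with an estimated correlation), nuclear oxidative phosphorylation subunits (73 genes, 0.12, adjusted p = 0.823 with an estimated correlation), complement and MHC class I (0.25, adjusted p = 0.496 with an estimated correlation) and oligodendrocyte precursors (0.26, adjusted p = 0.245 with an estimated correlation). Lower were synaptic transmission (−0.14, adjusted p = 0.566 with an estimated correlation), the circadian clock (−0.23, adjusted p = 0.245 with an estimated correlation), cholesterol synthesis (−0.23, adjusted p = 0.496 with an estimated correlation), GABAergic interneurons (−0.19, adjusted p = 0.529 with an estimated correlation) and neocortex (−0.38, adjusted p = 0.245 with an estimated correlation). In these 9 lists no member passed over all genes tested, and by exact permutation their adjusted p lay between 0.107 and 0.521. Camera lost interneurons without any of 8 libraries (mean −0.12 without 5M-CD 8 and −0.29, kept, without 5M-CD 9) and complement without 5M-CD 2, 8 or 9 or 15M-CD 2, 3 or 9 (0.16 without 15M-CD 2). It lost oxidative phosphorylation without 5M-CD 2 or 9 or 15M-CD 2 (0.07 to 0.08), synaptic transmission without 5M-CD 2 or 9 (−0.09) and precursors without 5M-CD 9 or 15M-CD 9. Over 8756 loci the differences of this comparison fell with log2 transcript length (correlation −0.221). The correlation was −0.154 for 18 versus 5 months in CD, and −0.309 and −0.327 for 15 and 18 versus 5 months under MR. No list test was rerun with that trend removed.

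With lane as a factor 14 loci passed in this comparison, and of the genes named here 1, Tmem254b/Tmem254c (−1.57). The immediate early list kept its call with lane as a factor (mean −0.45) and stood at −0.57 in lane 4, where 3 libraries of 15M-CD meet 1 of 5M-CD.

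The comparison of 18 with 5 months in CD asks the same of the oldest mice. Several genes of oligodendrocytes, the cells that make myelin, passed the test, though their list as a whole passed camera alone (adjusted p = 0.283 with an estimated correlation and 0.0616 by exact permutation). Cmtm5 rose from 7.13 ± 1.12 (SD, n = 6) to 12.3 ± 1.45 FPKM (n = 8), a difference of 0.71 (SE 0.13, adjusted p = 0.00606), and Olig2, the transcription factor of the oligodendrocyte lineage, from 5.96 ± 1.02 to 10.1 ± 1.65 FPKM (0.68, SE 0.134, adjusted p = 0.0124). The gap junction gene Gjb1 (1.10, SE 0.23, adjusted p = 0.0211), the transferrin gene Trf (1.09, SE 0.246, adjusted p = 0.0333), Ppp1r14a (1.23, SE 0.264, adjusted p = 0.0283) and the small heat shock protein gene Cryab (0.95, SE 0.214, adjusted p = 0.0333) rose as well. The complement locus C4a/C4b, merged in the table and so not assignable to either gene, rose from 2.44 ± 0.742 to 9.04 ± 4.99 FPKM (1.40, SE 0.26, adjusted p = 0.00645). Olfml3 was again higher (0.61, SE 0.133, adjusted p = 0.0283), as was Cyba, a subunit of the phagocyte NADPH oxidase (0.71, SE 0.159, adjusted p = 0.0333).

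Among the genes that fell, Fos was at 3.51 ± 0.453 FPKM (n = 8), a difference of −0.98 (SE 0.151, adjusted p = 0.000446), with Junb (−0.77, SE 0.159, adjusted p = 0.0196), Ier2 (−0.59, SE 0.131, adjusted p = 0.0325) and Gadd45b (−0.75, SE 0.156, adjusted p = 0.0211). Sgk1, a kinase gene that glucocorticoids induce, fell from 29.7 ± 7.08 to 11.2 ± 4.39 FPKM (−1.38, SE 0.262, adjusted p = 0.0085), and the 1600002K03Rik/Cirbp locus fell as well (−0.78, SE 0.139, adjusted p = 0.00477). Plat, the tissue plasminogen activator, differed by −0.55 (SE 0.112, adjusted p = 0.0187) and the locus of Chrm4/Gm39876, which holds a muscarinic acetylcholine receptor gene, by −1.33 (SE 0.265, adjusted p = 0.0129).

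In all 17 loci rose and 13 fell, of which 3 higher ones have no symbol, and 2192 loci had an unadjusted p under 0.05. Leaving out 1 library moved the 30 loci for 18 versus 5 months in CD to between 7 and 50: 19, 11, 7 and 16 without 5M-CD 4, 6, 8 and 10, and 13, 11 and 50 without 18M-CD 7, 8 and 9. A fit of only these groups gave 13 and array weights 1697. The other named calls were Fkbp2 (0.45), Anxa5 (0.56), the merged locus Gm21992/Rbm14/Rbm4 (1.58), Prdm4 (−1.21) and Tubb5 (−2.24; 3 loci, uncertain). The named genes moved in 8 of 8 libraries of 18M-CD, except Junb, which did in 7 of 8. Of 22 named calls 7 held whichever library was left out: Cmtm5, C4a/C4b, Tubb5, Fos, Prdm4, 1600002K03Rik/Cirbp and Sgk1. Olig2 was lost only without 5M-CD 8 (adjusted p = 0.0504), and the other 14 without at least 1 of 5M-CD 2, 4, 6, 8, 9 and 10 and 18M-CD 1, 2, 6, 7 and 8. With lane as a factor 0 of the 13009 loci passed in limma, against 30, and 5M-CD and 18M-CD share no lane. Called at both 15 and 18 months were 6 loci (1 higher and 5 lower), in comparisons that share their 5-month libraries and so their error.

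Of the fixed lists, 4 differed between 18 and 5 months in CD by the exact permutation test, each at an adjusted p of 0.025. The immediate early genes (14 tested, mean −0.51; 3 fell, 9 adjusted over the list alone) and the glucocorticoid-induced genes (11 tested, mean −0.49; 1 fell, 4 adjusted over the list alone) were lower, each in 8 of 8 libraries. Complement and MHC class I (7 tested, mean 0.41; 0 over all genes tested, 4 higher adjusted over the list alone) was higher in 7 of 8 libraries and oligodendrocyte precursors (8 tested, mean 0.36; 1 rose, 5 adjusted over the list alone) in 8 of 8. Mature oligodendrocytes and myelin had the largest mean of the lists, 0.57, with 15 of 15 members above 0, 2 of them past the test and 6 adjusted over the list alone. Camera called it (adjusted p = 1.43e-06; adjusted p = 0.283 with an estimated correlation) and the exact permutation test gave an adjusted p of 0.0616. Mbp, the myelin basic protein gene, differed by 0.91 (adjusted p = 0.132), not past the test. Camera called 10 lists and none with an estimated correlation, where the adjusted p was 0.0791 for the immediate early genes and 0.19 for the glucocorticoid, complement and precursor lists. The other calls were ribosomal proteins (0.23, adjusted p = 0.479 with an estimated correlation), synaptic transmission (−0.16, adjusted p = 0.54 with an estimated correlation), the circadian clock (−0.24, adjusted p = 0.283 with an estimated correlation), disease-associated microglia (0.20) and homeostatic microglia (0.20), both with an adjusted p = 0.369 with an estimated correlation. By exact permutation these 5 had an adjusted p between 0.0616 and 0.473. Camera lost synaptic transmission without 5M-CD 2 or 9 or 18M-CD 5, 6 or 7 (−0.07 without 18M-CD 7), disease-associated microglia without 5M-CD 9 or 18M-CD 5, and homeostatic microglia and precursors without 5M-CD 9. The clock mean went to −0.16 without 18M-CD 7.

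Between 15 and 18 months in CD, 7 loci rose and 3 fell, 4 and 1 of them without a symbol, and 861 had an unadjusted p under 0.05. With 1 library left out there were 5 to 12 loci, with 6 without 15M-CD 2 or 3 or 18M-CD 2 or 9 and 5 without 18M-CD 1, and array weights gave 36. The merged locus of Tmem254b/Tmem254c rose by 1.12 (SE 0.177, adjusted p = 0.000481, 8 of 8 libraries), while Prdm4 (−0.99, SE 0.194, adjusted p = 0.0164, 7 of 8 libraries) and Pdhx, which has 2 loci (−1.85, SE 0.392, adjusted p = 0.0323), fell. The list of adult neurogenesis, of genes expressed while new neurons form (8 of 20 members tested), was lower at 18 months. Its score was 0.074 ± 0.178 (n = 8) in 15M-CD and −0.238 ± 0.121 (n = 8) in 18M-CD, lower in 8 of 8 libraries (exact permutation p = 0.00124, adjusted p = 0.0373), though camera did not call it (adjusted p = 0.0536; adjusted p = 0.25 with an estimated correlation). The myelin list (mean 0.36, camera adjusted p = 9.04e-06), disease-associated microglia (0.12) and the methionine cycle (−0.15) were called by camera, each with an adjusted p = 0.631 with an estimated correlation and between 0.323 and 0.658 by exact permutation. The myelin mean went to 0.24 without 15M-CD 4. The other 2 calls were lost without any of several libraries (5 for microglia, with a mean of 0.07 without 15M-CD 7 and 0.08 without 18M-CD 5, and 7 for the methionine cycle). Mbp (0.77), Cryab (0.54) and Cd52 (0.62) were not past the test. The call of Prdm4 was lost without 18M-CD 1, 5 or 6, and that of Pdhx without any of 13 libraries. In lane 3, where 1 library of 18M-CD meets 5 of 15M-CD, Prdm4 (0.13) and the myelin list (−0.12) had the other sign. The neurogenesis score there was −0.034 in 18M-CD 9, within the range of the 15M-CD libraries (−0.09 to 0.372). Lane and age can thus not be told apart for that list.

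**Figure D2:**
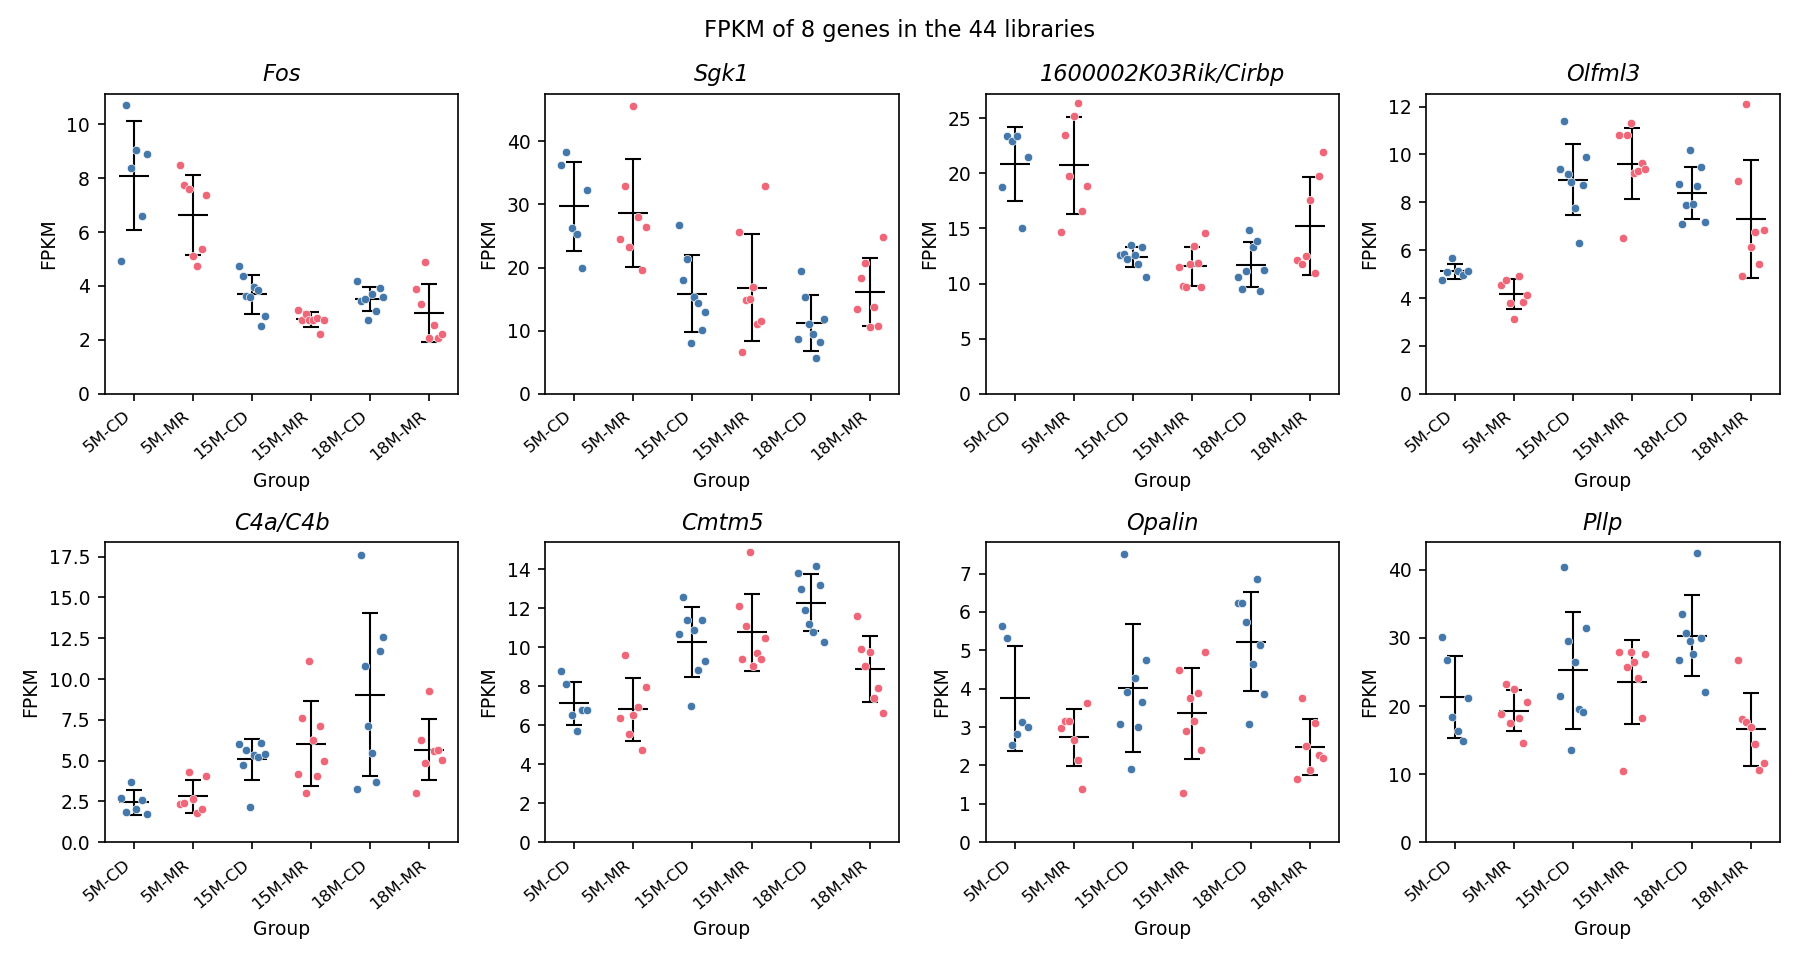
FPKM (y axis) of 8 genes or merged loci in the 44 libraries by group (x axis). Points are libraries, blue for CD and red for MR, and black lines the mean and SD of the group; Fos lies at 8.09 FPKM in 5M-CD and between 2.75 and 3.69 in the mean of each older group.

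MR was then compared with CD at each age, the comparison that asks what methionine restriction does to the hippocampus. At 5 months 0 of 13009 loci passed in limma (smallest adjusted p = 0.126; 600 loci had an unadjusted p under 0.05). For MR versus CD at 5 months array weights gave 406 loci, and quantile normalization, lane as a factor and the sample numbers as a block 2 to 3. The smallest p belonged to Tubb5 (−1.69, SE 0.335, adjusted p = 0.126; 3 loci, uncertain), followed by Plxna1, a semaphorin receptor (1.18, SE 0.259, adjusted p = 0.196), Hinfp (1.33), Smad4, the shared mediator of TGF-beta signals (1.45, SE 0.336, adjusted p = 0.255), and the merged locus Ago1/Ago3/Ago4/Tekt2 (1.69). All 5 differences were seen in 7 of 7 libraries of 5M-MR. Some passed when 1 library was left out: Tubb5 without 5M-CD 9 or 5M-MR 4, Plxna1 without 5M-CD 9 or 10, Smad4 without 5M-CD 10 and Hinfp without 5M-MR 4. Of the receptors for the hormone FGF21, Fgfr1 differed by 0.34 (SE 0.165, adjusted p = 0.937), Fgfr2 by −0.24 (SE 0.209) and Fgfr3 by 0.09 (SE 0.172, adjusted p = 0.945). The sign of Fgfr3 turned with lane as a factor (−0.001). Fgf21, its co-receptor gene Klb and Fgfr4 are not listed under a symbol in the table, so they were not analysed here. Camera called synaptic transmission higher (44 genes, mean 0.14, 33 above 0, adjusted p = 0.00951; adjusted p = 0.941 with an estimated correlation and 0.746 by exact permutation), a call lost without 5M-CD 8 (mean 0.09), with 0 members past the test over all genes or adjusted over the list alone. Cplx1, a regulator of vesicle release, differed by 0.78, not past the test. By exact permutation 3 lists had an unadjusted p under 0.05 and none passed: the methionine cycle (0.20, adjusted p = 0.157), glucocorticoid-induced genes (0.16, adjusted p = 0.169) and reactive astrocytes (−0.32, adjusted p = 0.169). Of the 7 astrocyte genes tested, Lcn2 was at 5.27 ± 4 FPKM (SD, range 0.216 to 9.63) in 5M-CD and 0.264 ± 0.291 in 5M-MR. This 1 variable gene may hold much of the mean of that list, which was not tested without it. In the same groups the share of loci without a symbol differed by −1.25 points (exact permutation p = 0.0187, adjusted p = 0.0559), the mitochondrial rRNA share by −1.74 (adjusted p = 0.0927) and the loci at 0 by −43.9 (adjusted p = 0.0708), none past the test. In lane 1, where 2 libraries of 5M-MR meet 5 of 5M-CD, 11 loci passed.

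At 15 months 0 loci passed in limma (smallest adjusted p = 0.296, at a locus without a named gene; 295 had an unadjusted p under 0.05). Array weights and replicate as a block gave 1 each. The named genes with the smallest p were Mettl1, which methylates tRNA (0.90, SE 0.222, adjusted p = 1), Sema6d (−1.02), Poli (−1.39), Rmdn1 (0.93) and Capg (−1.09). Fgfr1 (0.06), Fgfr2 (−0.22) and Fgfr3 (0.10) were not past the test (adjusted p = 1). The list of the methionine cycle, transsulfuration and glutathione synthesis, the pathway that methionine enters, had 15 of 15 members below 0 with a mean of −0.15 (camera adjusted p = 0.00882; adjusted p = 0.617 with an estimated correlation; exact permutation p = 0.0443, adjusted p = 0.685). Camera also called dentate gyrus granule cells (−0.32, adjusted p = 0.00774), pericytes, smooth muscle and fibroblasts (0.31, adjusted p = 0.0104) and immediate early genes (−0.15, adjusted p = 0.0283), each with an adjusted p = 0.617 with an estimated correlation and between 0.685 and 0.735 by exact permutation. Without 15M-MR 5 the granule cell and pericyte means went to −0.18 and 0.18, and both calls were lost. The pericyte call was also lost without 15M-CD 6 or 7 or 15M-MR 4 or 8 (0.19 without 15M-MR 8; 0.47, kept, without 15M-CD 8), and that of immediate early genes without 15M-CD 1 or 7 or 15M-MR 4, 6, 7 or 8. None of the 4 lists had a member past the test, over all genes or adjusted over the list alone. Prox1, a marker of granule cells, stood at −1.20, the pericyte gene Vtn at 0.43, Fos at −0.31 and Amd1 at −0.16, not past the test. Amd1 turned to 0.144 with lane as a factor. None of the 4 calls held with lane as a factor (camera adjusted p from 0.164 to 0.983), and in lane 4, with 8 libraries of 15M-MR against 3 of 15M-CD, the methionine cycle list stood at −0.04 and 2 loci passed.

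At 18 months, myelin genes were lower under MR in every member tested, without a gene past the test. Opalin, a membrane protein of myelinating cells, was at 2.48 ± 0.733 FPKM (SD, n = 7) in 18M-MR and 5.22 ± 1.3 (n = 8) in 18M-CD (−0.83, SE 0.199, adjusted p = 0.314). Mag, the myelin-associated glycoprotein, was at 18.1 ± 2.83 and 36.1 ± 12 FPKM (−0.91, SE 0.248, adjusted p = 0.452). Pllp, a gene of myelin (−0.87, SE 0.194), and Gjb1 (−0.92, SE 0.22) had an adjusted p of 0.314, and with Opalin were lower in 7 of 7 libraries. The myelin list had 15 of 15 members below 0 with a mean of −0.57, 0 members past the test over all genes and 6 lower adjusted over the list alone (camera adjusted p = 2.3e-11; adjusted p = 0.109 with an estimated correlation). The list of oligodendrocyte precursors and newly formed oligodendrocytes, with Olig2 (−0.42, SE 0.128, adjusted p = 0.601) and Olig1 (−0.46), had 8 of 8 below 0, a mean of −0.37 and 2 lower adjusted over the list alone (camera adjusted p = 0.000139; adjusted p = 0.0424 with an estimated correlation). Glucocorticoid-induced genes were higher: 10 of 11 lay above 0 with a mean of 0.37, 1 higher adjusted over the list alone (camera adjusted p = 1.67e-06; adjusted p = 0.0424 with an estimated correlation), among them Sgk1 (0.50) and, each with 2 loci and so uncertain, Cdkn1a (1.0, SE 0.278, adjusted p = 0.452) and Fkbp5 (0.96).

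In 18M-MR all 3 scores lay beyond the 18M-CD mean in 7 of 7 libraries. By exact permutation p was 0.00528 for glucocorticoid-induced genes, 0.00793 for myelin and 0.00746 for precursors, each with an adjusted p of 0.0793 over 30 lists, so the 3 differences passed camera and not this test. Among the marker scores of cell types, planned as 70 tests in 5 comparisons, myelin and precursors had an adjusted p of 0.0555 by exact permutation. That value is adjusted over the cell types of this comparison alone, not over the 70 tests. With lane as a factor the myelin list stood at −0.29 (camera adjusted p = 0.228), the precursors at −0.20 (adjusted p = 0.465) and the glucocorticoid list, which kept its camera call, at 0.42. In lane 3, where 6 libraries of 18M-MR meet 1 of 18M-CD, they stood at −0.27, −0.13 and 0.39. Camera called 3 further lists lower, none with a member past the test: heat shock proteins (−0.17, adjusted p = 0.00963), homeostatic microglia (−0.26, adjusted p = 0.00963), both with an adjusted p = 0.471 with an estimated correlation, and disease-associated microglia (−0.18, adjusted p = 0.033; adjusted p = 0.542 with an estimated correlation). By exact permutation these 3 had an adjusted p of 0.431. Their examples Lpl (−1.02, SE 0.299, adjusted p = 0.478), Gpr34 (−1.08) and Cryab (−0.53) were not past the test. Heat shock proteins were lost without 18M-CD 5 or 18M-MR 2 or 7, homeostatic microglia without 18M-MR 6 or 7, and disease-associated microglia without 18M-CD 5 or 7 or 18M-MR 2, 5, 6 or 7. Fgfr1 (−0.25), Fgfr2 (−0.40, adjusted p = 1) and Fgfr3 (0.01) were not past the test. In limma 0 loci passed (smallest adjusted p = 0.314; 610 had an unadjusted p under 0.05), against 14 with the share of loci without a symbol as a covariate, 2 with lane as a factor and 17 in lane 3 alone, where 6 libraries of 18M-MR meet 1 of 18M-CD (MR versus CD at 18 months).

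**Figure D3:**
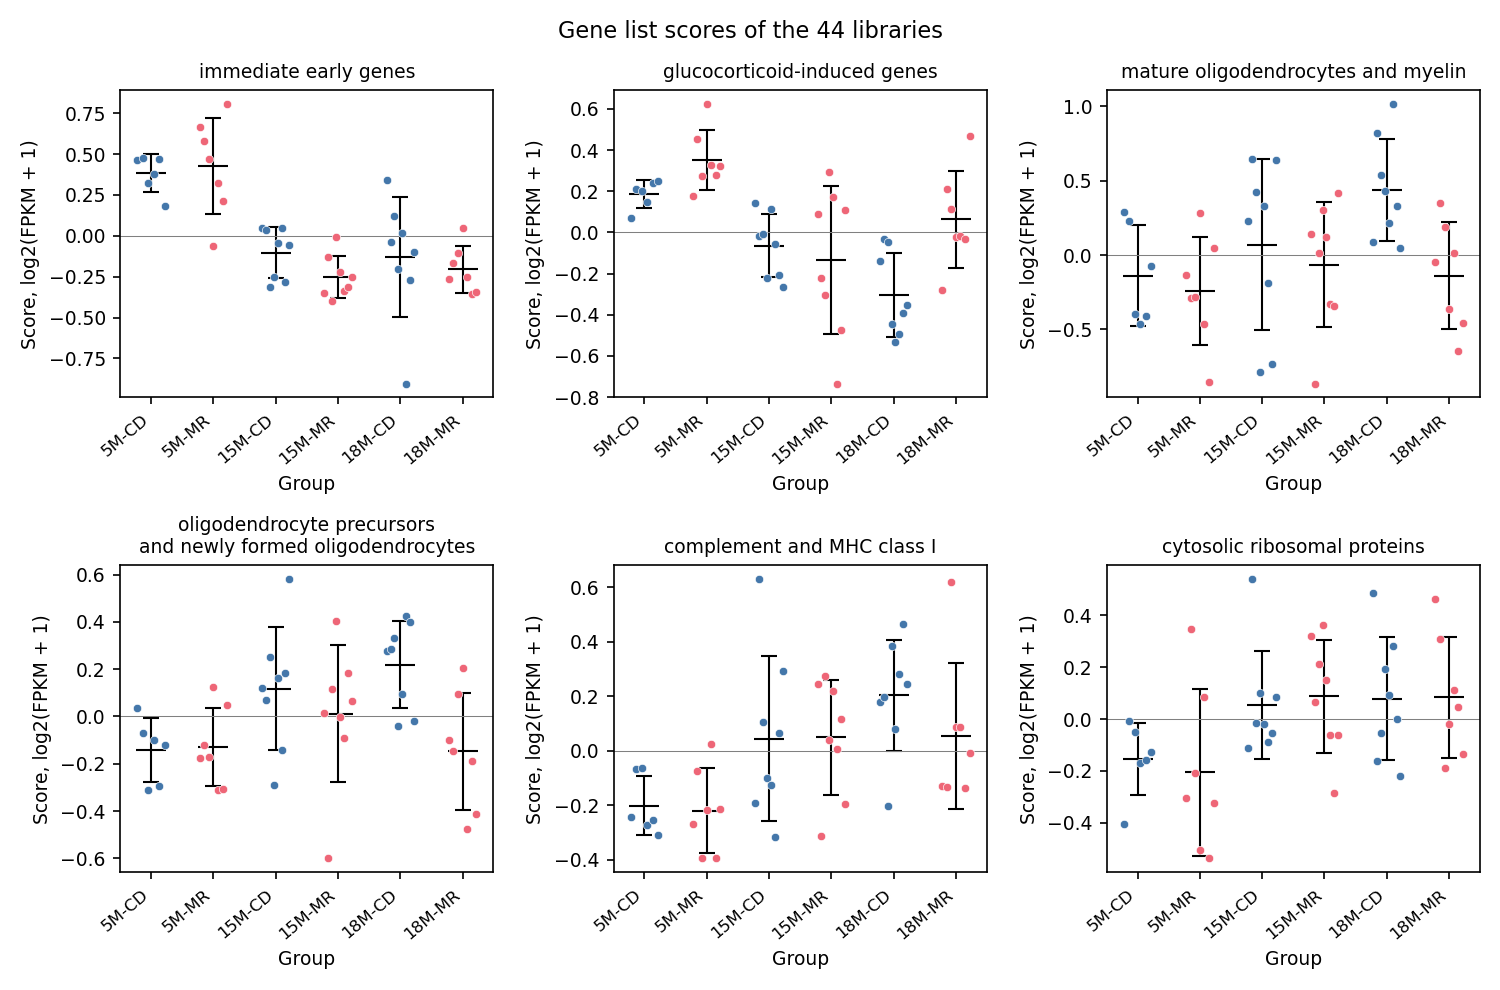
Scores of 6 gene lists (y axis, mean of the centred log2(FPKM + 1) values of the members) in the 44 libraries by group (x axis). Points are libraries, blue for CD and red for MR, and black lines the mean and SD of the group; the mean myelin score is 0.434 in 18M-CD and −0.139 in 18M-MR.

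Averaged over the 3 ages, 0 loci differed between MR and CD in limma (smallest adjusted p = 0.999; 329 had an unadjusted p under 0.05). The smallest p were those of Scn3a (−0.76, SE 0.186), Opalin (−0.45, SE 0.117), Smarcad1 (−0.72), Sema6d (−0.67) and Upp2 (−0.75), all at an adjusted p of 0.999. Fgfr1 stood at 0.05, Fgfr2 at −0.29 (adjusted p = 0.999) and Fgfr3 at 0.07. Camera called myelin (−0.27, adjusted p = 1.74e-09; adjusted p = 0.191 with an estimated correlation; 1 lower adjusted over the list alone), and precursors (−0.15, adjusted p = 0.00195; adjusted p = 0.161 with an estimated correlation). It also called glucocorticoid-induced genes (0.15, adjusted p = 9.98e-05; adjusted p = 0.161 with an estimated correlation; 1 higher adjusted over the list alone) and synaptic transmission (0.07, adjusted p = 0.000644; adjusted p = 0.402 with an estimated correlation). With lane as a factor the calls of precursors and synaptic transmission were lost, and no exact permutation test was run on this average. The mean of synaptic transmission went to 0.04 without 18M-CD 7. For the interaction of MR with age, too, 0 loci passed in limma (smallest adjusted p = 0.14, Tubb5, uncertain as above; 540 had an unadjusted p under 0.05). For the MR by age interaction array weights gave 23, the share of loci without a symbol as a covariate 7, lane as a factor 3 and replicate as a block 2, and of simulated interactions of a factor of 2 the procedure recovered 32.8%. Smad4, Lcn2, Ppox and Fkbp5 (2 loci, uncertain) followed at an adjusted p of 0.675.

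The comparison of 15 with 5 months under MR gave many more loci than in CD: 1547 rose, 1109 of them without a symbol, and 840 fell, 800 of them with one. Beside these counts stands the higher share of loci without a symbol at 15 months, and with lane as a factor 14 loci passed, against 2387. The groups share no lane. Leaving out 1 library gave 1455 to 2375 loci for 15 versus 5 months in MR, with 1455 and 1465 without 5M-MR 6 and 8, and array weights gave 4708. Fos (−1.0, SE 0.144, adjusted p = 3.26e-05), Egr4 (−1.13, SE 0.181, adjusted p = 0.00013), Egr1 (−1.26, SE 0.204, adjusted p = 0.000148) and Nr4a1 (−1.09, SE 0.186, adjusted p = 0.000331) fell, as did the clock genes Cry1 (−0.68, adjusted p = 0.00778) and Per1 (−0.93, adjusted p = 0.0112). Mat2a, which makes S-adenosylmethionine from methionine, with 2 loci and so uncertain (−0.70, SE 0.177, adjusted p = 0.00791), Asns, the asparagine synthetase (−0.57, adjusted p = 0.00738), and Slc7a1 (−0.53, adjusted p = 0.00966) fell too. Olfml3 (1.04, SE 0.127, adjusted p = 1.07e-06), the Fc receptor chain Fcer1g (0.72, SE 0.133, adjusted p = 0.000846), S100b (0.82, SE 0.154, adjusted p = 0.00121), Mt3 (0.69, SE 0.125, adjusted p = 0.000674) and Ogn (1.44, SE 0.265, adjusted p = 0.000896) rose. Each of these differences was seen in 8 of 8 libraries of 15M-MR. Klhl34 (−1.73), Tmem254b/Tmem254c (−1.56) and Entpd4/Gm21685 (−0.97) also fell. Of all named calls Tmem254b/Tmem254c and Klhl34 (both at an adjusted p = 0.0322) passed with lane as a factor.

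Of the 30 lists, 10 differed between 15 and 5 months under MR by exact permutation. Immediate early genes (mean −0.68; 7 of 14 fell, 11 adjusted over the list alone) and the methionine cycle (−0.24; 2 of 15 fell, 2 adjusted over the list alone) had an adjusted p of 0.00466. The circadian clock (−0.39; 6 of 16 fell, 7 adjusted over the list alone) and ATF4 targets (−0.27; 8 of 18 fell and 1 rose, 8 and 1 adjusted over the list alone) had one of 0.00699. Dentate gyrus granule cells (−0.58, adjusted p = 0.0149), synaptic transmission (−0.22) and glucocorticoid-induced genes (−0.49), both at 0.0163, and mitochondrial biogenesis and AMPK (−0.19, adjusted p = 0.041) were lower. Homeostatic microglia (0.40, adjusted p = 0.0155) and reactive astrocytes (0.29, adjusted p = 0.0285) were higher. Camera did not call the last 2 (adjusted p = 0.0631 and 0.272; adjusted p = 0.686 with an estimated correlation) or mitochondrial biogenesis and AMPK (adjusted p = 0.291; adjusted p = 0.693 with an estimated correlation). Camera called 9 lists and none with an estimated correlation, with an adjusted p = 0.0598 for the immediate early genes and an adjusted p from 0.179 to 0.693 for the others. Among them were ribosomal proteins (0.29; 23 of 68 rose, 27 adjusted over the list alone; adjusted p = 0.686 with an estimated correlation) and oxidative phosphorylation subunits (0.22; 21 of 73 rose and 3 fell; adjusted p = 0.693 with an estimated correlation), with an adjusted p of 0.134 and 0.173 by exact permutation. The methionine cycle call of camera was lost without 15M-MR 5. Of the 38 loci called in CD, all 38 had the same sign under MR and 35 were called there (9 higher and 26 lower, against 1.19 and 1.81 if independent). Any other difference between the 15-month and 5-month mice, or between their lanes, could recur in both diets. This agreement therefore cannot tell age from such a difference.

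Between 5 and 18 months under MR, 1995 loci rose, 1603 of them without a symbol, and 1821 fell. Without the libraries over 8% in loci without a symbol, among them 18M-MR 1, 2 and 7, 23 loci passed in place of 3816. Of the 21 named genes 6 passed there: Fos (−0.98), Fcer1g (0.88), Olfml3 (0.76), S100b (0.69), Ssx2ip, a centrosome gene (−0.66), and the merged locus Zfp783/Zfp956. With all libraries Fos differed by −0.95 (SE 0.149, adjusted p = 0.000503) and Fcer1g by 0.77 (SE 0.137, adjusted p = 0.00154), each in 7 of 7 libraries. Mat2a (−1.01, SE 0.182, adjusted p = 0.00175; uncertain), Fgfr1 (−0.62, SE 0.158, adjusted p = 0.00813), Fgfr3 (−0.46, SE 0.165, adjusted p = 0.0332), Camk2a (−0.83), Syt1 (−0.69) and Sdha (−0.55) were lower. The neutrophil genes S100a9 (1.48, adjusted p = 0.00704, 6 of 7 libraries) and S100a8 (1.44, adjusted p = 0.00878, 5 of 7 libraries) were higher. These 8 calls were made with all libraries and lost without those over 8%. Atrn (−0.89), Klhl34 (−1.60), TrnL1 (1.08), Stmn1-rs2 (0.97), Junb (−0.73), Rpl31 (0.65) and Ndufa2 (0.61) complete the named calls. Leaving out 18M-MR 1 or 2 moved the count for 18 versus 5 months in MR to 2253 or 1152. The call of Fgfr3 was lost without 5M-MR 6, 7 or 8 or 18M-MR 1, 2 or 6.

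By exact permutation the immediate early genes (mean −0.63, 7 of 7 libraries, adjusted p = 0.035; 6 of 14 fell, 9 adjusted over the list alone) and the methionine cycle (−0.38, 7 of 7 libraries, adjusted p = 0.0437; 6 of 15 fell, 6 adjusted over the list alone) were lower at 18 months under MR. The member counts of this comparison were made with all libraries. Without those over 8% in loci without a symbol, 23 loci in all passed in place of 3816. Camera called the immediate early and methionine cycle lists, each with an adjusted p = 0.654 with an estimated correlation. It also called ribosomal proteins (0.29; 23 of 68 rose; adjusted p = 0.691 with an estimated correlation), synaptic transmission (−0.27; 14 of 44 fell; adjusted p = 0.691 with an estimated correlation) and oxidative phosphorylation subunits (0.11; 11 of 73 rose and 6 fell; adjusted p = 0.858 with an estimated correlation), with an adjusted p of 0.16, 0.0546 and 0.541 by exact permutation. The call of oxidative phosphorylation was lost without any of 10 libraries, with means of 0.04 without 18M-MR 1 and 0.07 without 5M-MR 6 or 8 (0.18, kept, without 5M-MR 4). Between 15 and 18 months under MR, 13 loci rose and 4 fell (964 had an unadjusted p under 0.05). Leaving out 1 library gave 11 to 29, with 28, 29, 26, 11 and 27 without 18M-MR 1, 4, 5, 6 and 8. Array weights gave 11, lane as a factor 6, only the groups compared 4, a filter at 5 FPKM 8, quantile normalization 26 and the share of loci without a symbol as a covariate 165 (18 versus 15 months in MR). Tmem254b/Tmem254c rose by 1.06 (SE 0.184, adjusted p = 0.00198), while Lynx1, a modulator of nicotinic receptors (−0.82, SE 0.172, adjusted p = 0.022), Lhpp (−0.56, SE 0.122, adjusted p = 0.0328) and Ndn (−0.74, SE 0.165, adjusted p = 0.0463) fell. The last 3 calls were each lost without at least 1 library, all of them without 18M-MR 2 or 6. Camera called 6 lists there, among them CA2 and CA3 pyramidal cells (−0.43) and neocortex (0.28), both with an adjusted p = 0.404 with an estimated correlation. The others were homeostatic microglia (−0.36, adjusted p = 0.5 with an estimated correlation), cholesterol synthesis (−0.16, adjusted p = 0.594 with an estimated correlation), glucocorticoid-induced genes (0.20, adjusted p = 0.435 with an estimated correlation) and immediate early genes (0.05, adjusted p = 0.501 with an estimated correlation). The CA2 and CA3 mean went to −0.28 without 18M-MR 2, whose score was −1.126 against −0.371 for the next lowest of the group, and stayed called, though without the 6 libraries over 8% the call was lost (adjusted p = 0.229, list CA2 and CA3 pyramidal cells in 18 versus 15 months in MR). The calls of microglia, cholesterol synthesis, glucocorticoid-induced and immediate early genes were each lost without any of 4 to 7 libraries, with means as low in size as −0.08 for cholesterol synthesis (without 18M-MR 2), 0.11 for glucocorticoid-induced genes (without 15M-MR 7) and 0.004 for immediate early genes (without 18M-MR 5). None of the 6 had a member past the test, and 0 lists passed by exact permutation (adjusted p between 0.258 and 0.739 for these 6; 4 of the 30 had an unadjusted p under 0.05).

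**Figure D4:**
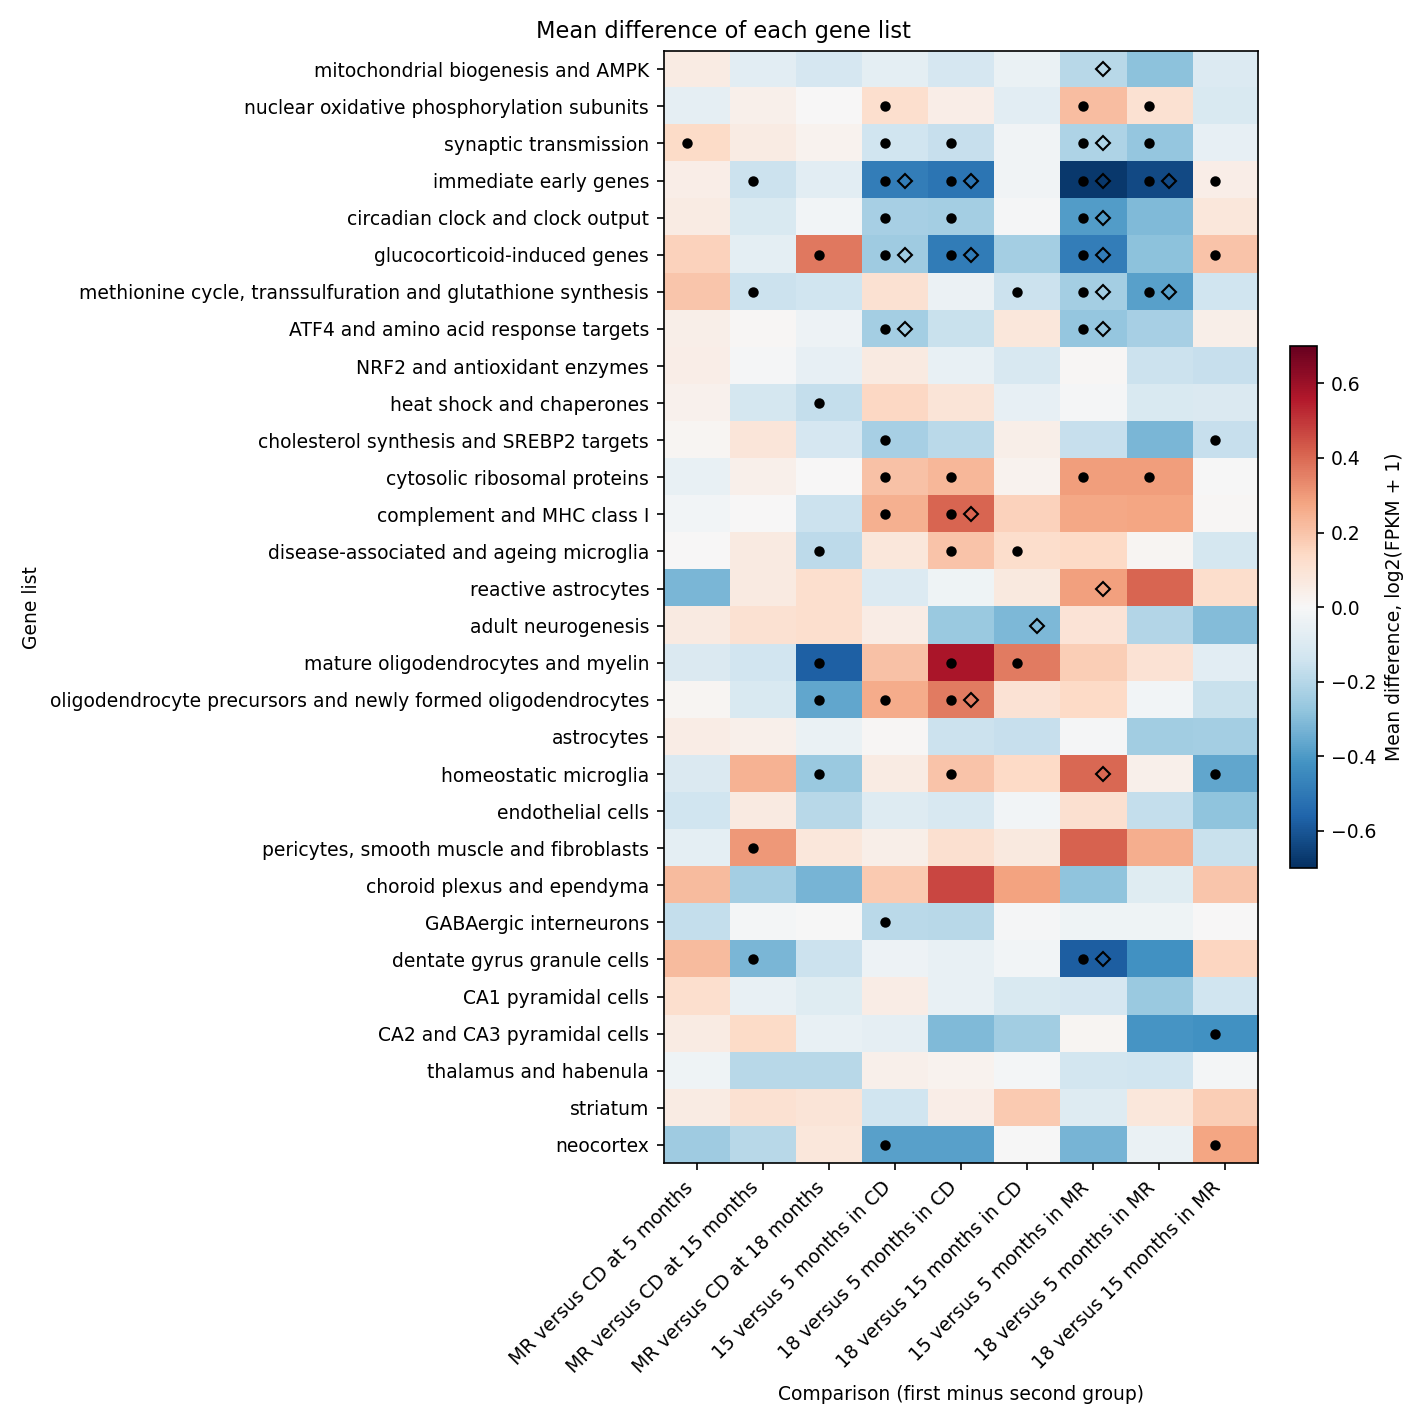
Mean difference of log2(FPKM + 1) (colour) of 30 gene lists (y axis) in 9 comparisons (x axis). Dots mark an adjusted p under 0.05 by camera with the preset correlation and open diamonds one by the exact permutation test of library scores; immediate early genes carry both marks in the 4 comparisons with 5 months.

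Whether MR moved genes against their change with age was asked at 15 and 18 months. Myelin genes and glucocorticoid-induced genes had opposite signs in these comparisons at 18 months. The means were 0.57 and −0.49 with age in CD and −0.57 and 0.37 with MR. Both differences share their CD libraries, so a chance error in them enters both with opposite sign. Of the 30 loci that changed with age in CD at 18 months 27 had the opposite sign under MR (90%), and of the 38 at 15 months 23 (60.5%). With as many loci ranked on 4 CD libraries of that age and the MR difference taken against the other 4, the shares were 60.6% (range 33.3 to 83.3 over 70 divisions) and 43.6% (23.7 to 55.3). Over all loci they were 42% and 38%. Across the 13009 loci, which are not independent replicates, the correlation of the age change with the MR change was −0.116 at 15 months and −0.163 at 18 months. Simulated data with no age or MR effect and loci varying independently gave −0.466 and −0.445. Residuals of the real libraries, dealt at random to the groups, gave −0.469 (SD 0.146) and −0.429 (SD 0.153). The observed covariances (−0.0111 and −0.0195) lay within the ranges of those residuals (−0.167 to −0.00357 and −0.156 to 0.000346). Neither reference holds an age change, which alone would move the correlation, so they cannot show an effect of MR. With the shared libraries divided, so that no library served both differences, the correlation was 0.20 (range 0.148 to 0.314 over 35 splits) and 0.12 (0.068 to 0.209), so the sign turned. Called in both comparisons were 0 loci at either age.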

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

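All tests of an explanation below were chosen after the results were seen, and so were the list tests of differences between ages.

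Many loci differed between 5 months and the older ages under MR, 3816 at 18 and 2387 at 15 months, and most of the higher ones have no symbol. Argued against at 15 months, for loci with a symbol, are length and GC content (737 with each library's trend removed, against 781 of the same set without). The only library of that comparison with over 8% of its signal in loci without a symbol was 15M-MR 5. Without all libraries over that limit, most of them of other groups, 2792 loci passed, so 15M-MR 5 does not account for the count. Lane at 18 months stays open. With lane as a factor 3743 loci passed, but 5M-MR and 18M-MR meet only in lane 1, through 18M-MR 2, with 12% in loci without a symbol. The lane fit thus rests on that library and on other groups, and cannot decide. At 18 months leaving out the libraries over that limit left 23, so that a few libraries of another RNA composition may account for most of the count there (leaving out 18M-MR 1, 2 and 7 alone left 20, fewer than 33 of the 34 other sets of 3, whose median was 2070.5 and lowest 12). Open stay length and GC content at 18 months (762 loci of 1591, between the bounds set) and RNA composition across the whole group at both ages. With the share of loci without a symbol as a covariate 15 versus 5 months in MR gave 1045 loci, and the median size went from 0.785 to 0.423. For 18 versus 5 months in MR the median size went from 0.774 to 0.205, and 78.7% of the loci kept their sign. Open too is lane at 15 months, where 14 loci passed with lane as a factor. There the median size went to 0.619 and the SE from 0.235 to 0.42, so that lane and age cannot be told apart. Age itself, the biological explanation of the design, stays open at both ages and was not tested apart from these.

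A set of 10 loci was near 0 in all 16 libraries of 15 months, with a summed FPKM of at most 0.862, against 18.4 to 66.3 in the 13 libraries of 5 months and 0.437 to 43 in the 15 of 18 months, where 18M-CD 3 (0.437) and 18M-MR 1 (2.11) were low as well. Lane is argued against, since 6 of the 7 libraries of 18 months on the lane shared with 15-month libraries held these loci at over 5 times the highest 15-month library, and so is a steady effect of age, since 13 of all 15 libraries of 18 months did. Reads moved to near-identical copies stay open: the 1 locus that appeared gained 14.5% of the FPKM lost, but copies already expressed, or outside the loci of the table, would not show in that value. Of the 10 loci 6 lie within 30 consecutive locus numbers (at most 3 in 1000 random sets), among them Gm13304 (chromosome 4, 42114787 to 42115917) and Gm10601/Gm21075/Gm29801/Gm29804 (chromosome 4, 41805506 to 41893163). A deletion or other variant in the animals of 15 months, which 18M-CD 3 and 18M-MR 1 may carry too, is a candidate explanation, found and tested on the same data, and under it the ages would differ in more than age. The loci of this set may be among the calls between 15 and 5 months and between 18 and 15 months in either diet. How many of those calls they make up was not counted. The means of Gabra2 and of Tmem254b/Tmem254c also moved by 15 months and back towards the 5-month level by 18 months in both diets. Whether they share a cause with these loci was not tested.

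Myelin and oligodendrocyte precursor lists lay lower under MR at 18 months (means −0.57 and −0.37), called by camera with no member past the test over all genes and not called by exact permutation (adjusted p = 0.0793 for both), myelin also not with an estimated correlation (adjusted p = 0.109). The libraries over 8% in loci without a symbol are argued against as the cause, since without them the myelin mean was −0.605. Lane stays open, because 7 of 8 libraries of 18M-CD lie on lane 2 and none of 18M-MR does: with lane as a factor the mean was −0.29 (camera adjusted p = 0.228), so that lane and MR cannot be told apart here. A smaller share of white matter in the dissected tissue could also lower these genes, and the markers of hippocampal neurons, which would then be higher, differed by −0.069 (SE 0.154, 38 markers), too wide to decide. An effect of MR on oligodendrocytes stays among the open explanations as a hypothesis.

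Of 100 splits of the libraries into groups of the same sizes, only the real one gave as many loci called between ages in CD and between 15 and 5 months under MR. So few splits cannot show a share below 1 in 100 for each comparison. Random splits also break the link of lane with age, so they cannot tell age from lane or other differences between the batches of animals. In CD the loci called were 38 against at most 2 in another split for 15 against 5 months (1 split as large, the real one), 30 against 2 for 18 against 5 months (1) and 10 against 3 for 18 against 15 months (1). Under MR they were 2387 against 81 for 15 against 5 months (1). For 18 against 5 months under MR (3816 against 4191; 2 splits as large) and 18 against 15 months under MR (17 against 2423; 4) the share lies under 0.05 for each comparison alone, but other splits gave more loci, so these counts are not beyond what other groupings give. Chance could not be excluded for the loci with an unadjusted p under 0.05 between MR and CD. These were 600 against up to 1826 at 5 months (11 splits as large), 295 against 3455 at 15 months (74) and 610 against 5978 at 18 months (61). They were 329 against 4647 over the 3 ages (63) and 540 against 2821 for the interaction (36). Splits with several times the real count point to a structure of the samples. For MR at 18 months and for 18 against 5 and 18 against 15 months under MR, the split with the most loci called was also the one with the largest difference in the share of loci without a symbol.

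Nor could chance be excluded for the number of lists that camera called with the preset correlation: 1 against up to 10 at 5 months (96 splits as large), 4 against 14 at 15 months (76), 6 against 16 at 18 months (36) and 4 against 14 over the 3 ages (71) for MR against CD. For the ages in CD it was 12 against 15 for 15 against 5 months (5), 10 against 14 for 18 against 5 months (10) and 3 against 14 for 18 against 15 months (88), and under MR 9 against 12 (10), 5 against 11 (45) and 6 against 15 (34) for the same pairs.

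The MR difference of a list itself differed between ages in 13 of 90 tests, over 10 lists, in camera with the preset correlation, and in none with an estimated correlation (smallest adjusted p = 0.187). Between 5 and 15 months the MR difference of the methionine cycle moved by −0.344 (adjusted p = 0.00203; adjusted p = 0.406 with an estimated correlation) and that of dentate granule cells by −0.541 (adjusted p = 0.0144; adjusted p = 0.852 with an estimated correlation). Between 5 and 18 months it moved by −0.337 for the methionine cycle (adjusted p = 0.0397) and by −0.469 for myelin (adjusted p = 0.0147), both with an adjusted p = 0.855 with an estimated correlation. Between 15 and 18 months it moved up by 0.437 for glucocorticoid-induced genes (adjusted p = 0.000119; adjusted p = 0.187 with an estimated correlation), 0.277 for neocortex, 0.169 for dentate granule cells (adjusted p = 0.724 with an estimated correlation) and 0.088 for the circadian clock. Over the same ages it moved by −0.436 for myelin (adjusted p = 0.000119), −0.5 for homeostatic microglia (adjusted p = 0.00027; adjusted p = 0.348 with an estimated correlation), −0.26 for oligodendrocyte precursors, −0.247 for disease-associated microglia and −0.201 for cholesterol synthesis (adjusted p = 0.00707; adjusted p = 0.428 with an estimated correlation). For myelin, precursors, disease-associated microglia, neocortex and the clock the adjusted p was 0.387 with an estimated correlation.

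In 228 groups of libraries tested over 38 measures, 22 held 1 library far from the others by Dixon's test, where chance gives about 1 in 20, or 11.4. The FPKM sum was 282300 in 15M-CD 2. Ttr was at 12.3 on the log2(FPKM + 1) scale in 5M-CD 10, where the choroid plexus score was 2.06, and that score was 2.08 in 15M-CD 2. In 18M-MR 4 the homeostatic microglia score was 0.563 and the endothelial score 0.407. In 15M-CD 8 the score of pericytes, smooth muscle and fibroblasts was 1.09 and that of CA1 pyramidal cells −0.45. The dentate granule cell score was 0.758 in 5M-MR 10, the CA2 and CA3 score −1.13 in 18M-MR 2 and the striatum score 1.32 in 18M-MR 7. On the log2(FPKM + 1) scale Fos was at 1.68 in 15M-MR 8, Olfml3 at 2.9 and Pllp at 3.52 in 15M-MR 3, C4a/C4b at 1.67 in 15M-CD 4, and Olig2 at 2.34 and Tubb5 (3 loci, uncertain) at 3.31 in 5M-CD 9. Prdm4 was at 1.75 in 5M-MR 4, Cdkn1a (2 loci, uncertain) at 0 in 18M-CD 6, Serpina3g/Serpina3n at 5.18 in 5M-CD 2, Gabra2 at 1.56 in 18M-CD 1 and Lcn2 at 0.917 in 5M-MR 6.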

How the results depend on the processing

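Added after the data were seen were the alternatives with the share of loci without a symbol, loci with a symbol, the 6 libraries, Ttr, length and GC content, the shared lane, merged loci and lists without 1 library. The others were planned. Under the alternatives other than leaving out a library, the 180 values of named genes were computed 2259 times. Of these 1979 kept direction and side of the threshold, 205 lost a call, 58 gained one and 17 turned sign. Of 555 list values 417 kept both, 137 lost the call and 1 turned sign. Leaving out 1 library, 2769 of 2960 gene values and 894 of 994 list values kept both, and 168 and 100 lost the call. Of 174 counts 102 stayed within 1.5 times the main count, and with no filter all did. The cause of a change was not tested, except that fewer loci or libraries enter by construction where a setting leaves them out. Depth is unknown, so what it limits could not be given.

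With a pseudocount of 0.1, 18 versus 15 months in CD gave 16 loci, and 0 marker scores passed in place of 1. With the median 2 did. With at least 5 FPKM, 18 versus 5 months in CD gave 47, 18 versus 15 months in CD 6, 15 versus 5 months in MR 1390, 18 versus 5 months in MR 2209 and 18 versus 15 months in MR 8. Quantile normalization gave 2 for MR at 5 months, 65 for 18 versus 5 months in CD, 26 for 18 versus 15 months in MR, 1 for the interaction and 23 MR list calls in place of 15. A fit of only the groups compared gave 13 for 18 versus 5 months in CD, 3 for 18 versus 15 months in CD, 3755 for 15 versus 5 months in MR, 339 for 18 versus 5 months in MR and 4 for 18 versus 15 months in MR.

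Lane as a factor gave 3 for MR at 5 months, 2 at 18 months and 3 for the interaction, 14 for 15 versus 5 months in CD, 0 for 18 versus 5 months in CD, 14 for 15 versus 5 months in MR and 6 for 18 versus 15 months in MR. It turned Fgfr3 at 5 months (−0.001) and 18 months (−0.051), Amd1 at 15 months (0.144), Sox10 at 18 months (0.111), Fgfr1 over the 3 ages (−0.022) and the myelin list between 15 and 18 months in CD (−0.034). The libraries of the 1 shared lane gave 11, 2 and 17 for MR at 5, 15 and 18 months, 0 for 15 versus 5 months in CD, 125 for 18 versus 15 months in CD and 0 for 18 versus 5 months in MR. These fits are small, with 2 libraries against 5 for MR at 5 months and 8 against 3 at 15 months. In the other 4 an arm holds 1 library, assumed to vary like the other arm (6 against 1 for MR at 18 months, 3 against 1, 1 against 5 and 1 against 2 for the ages), so their counts and signs say little about stability. In that lane Fgfr3 stood at −0.16 (5 months) and −0.152 (18 months), Amd1 at 0.13, Sox10 at 0.278, Prdm4 (18 versus 15 months in CD) at 0.131 and S100a8 (18 versus 5 months in MR) at −0.108. Of lists, interneurons in 15 versus 5 months in CD stood at 0.009, disease-associated microglia and myelin in 18 versus 15 months in CD at −0.04 and −0.12, and oxidative phosphorylation in 18 versus 5 months in MR at −0.387.

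The sample numbers as a block gave 3 for MR at 5 months, 1 at 15 months, 2 for the interaction, 28 MR list calls and Fgfr3 at −0.051 at 18 months. The deviations of the 17 pairs of libraries with a shared number correlated between −0.422 and 0.241, 3 of them over 0.1, so the numbers were not used as pairs elsewhere. Array weights gave 406 and 1 for MR at 5 and 15 months, and 23 for the interaction. They gave 230 for 15 versus 5 months in CD, 1697 for 18 versus 5 months in CD, 36 for 18 versus 15 months in CD, 4708 for 15 versus 5 months in MR and 11 for 18 versus 15 months in MR. Fgfr3 stood at −0.061, −0.105 and −0.012 at 5 months, 18 months and over the ages. An estimated correlation left 2 of 15 MR list calls and 1 of 45 for ages.

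The share of loci without a symbol as a covariate gave 2, 14 and 7 for MR at 5 months, at 18 months and the interaction. It gave 68 for 15 versus 5 months in CD, 136 for 18 versus 5 months in CD, 1045 for 15 versus 5 months in MR, 25 for 18 versus 5 months in MR and 165 for 18 versus 15 months in MR. Only loci with a symbol gave 22 for 15 versus 5 months in CD, 3 for 18 versus 15 months in CD 906 for 15 versus 5 months in MR, 1828 for 18 versus 5 months in MR and 8 for 18 versus 15 months in MR. Without the 6 libraries 18 versus 5 months in MR gave 23. With Ttr as a covariate Fgfr3 at 18 months stood at −0.012. With the length and GC trend removed, MR at 5 and 18 months and the interaction gave 1 each, 18 versus 5 months in CD 96, 18 versus 15 months in CD 2, 15 versus 5 months in MR 737, 18 versus 5 months in MR 762 and 18 versus 15 months in MR 3. Fgfr3 at 5 months stood at −0.065. The same loci with no trend removed gave 13 for 15 versus 5 months in CD, 2 for 18 versus 15 months in CD 781 for 15 versus 5 months in MR, 1591 for 18 versus 5 months in MR and 2 for 18 versus 15 months in MR. With shared controls divided between the 2 differences, the correlation of age and MR change was 0.2 at 15 and 0.121 at 18 months.

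Leaving out 1 library, MR at 5 months gave 0 to 3 loci (2 without 5M-CD 2 or 9, 3 without 5M-CD 10 or 5M-MR 4, 1 without 5M-MR 7). MR at 15 months gave 0 to 1 (15M-MR 15), MR at 18 months 0 to 1 (18M-CD 9), MR over the ages 0 and the interaction 0 to 1 (5M-CD 9, 18M-MR 6). 15 versus 5 months in CD gave 28 to 44. 18 versus 5 months in CD gave 7 to 50, with 19, 11, 7 and 16 without 5M-CD 4, 6, 8 and 10, and 13, 11 and 50 without 18M-CD 7, 8 and 9. 18 versus 15 months in CD gave 5 to 12, with 6 without 15M-CD 2 or 3 or 18M-CD 2 or 9 and 5 without 18M-CD 1. For 15 versus 5 months in MR the range was 1455 to 2375, with 1455 and 1465 without 5M-MR 6 and 8. For 18 versus 5 months in MR it was 1152 to 5032, with 2253 and 1152 without 18M-MR 1 and 2. For 18 versus 15 months in MR it was 11 to 29, with 28, 29, 26, 11 and 27 without 18M-MR 1, 4, 5, 6 and 8. Fgfr3 ranged from −0.002 (without 5M-MR 8) to 0.154 at 5 months and from −0.114 (without 18M-MR 4) to 0.169 at 18 months, below 0 there also without 18M-CD 5 or 7 or 18M-MR 5, 7 or 8.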

Other observations

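The tests of single genes given here were planned, while Fos and Olfml3 were singled out for their levels after their values were seen. In lists with too few tested genes for a list test, single members are given as values. Of 4 interferon-stimulated genes tested (Bst2, Stat2, Lgals3bp and Ifi27) none passed in any comparison; in 18M-CD against 5M-CD Bst2 stood at 0.65 (adjusted p = 0.24) and Ifi27 at 0.43 (adjusted p = 0.212). Cdkn1a, which stops the cell cycle and is held by the senescence and the glucocorticoid lists, was lower at 15 than at 5 months under MR (−0.95, SE 0.278, adjusted p = 0.0175), with 2 loci and so uncertain. Of the replication-dependent histone genes, whose transcripts lack a poly(A) tail, Hist1h2bc rose there (0.70, SE 0.251, adjusted p = 0.0464). Of the blood cell markers, S100a8 and S100a9 passed between 18 and 5 months under MR, as the account of that comparison gives, while Alas2, an enzyme of haem synthesis in red cells, passed in none.

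The Fos locus (chromosome 12, 85473890 to 85477273) and the Olfml3 gene (chromosome 3, 103722222 to 103738001) were called at 15 and 18 months against 5 months in both diets. The merged locus 1600002K03Rik/Cirbp was the only other such locus. Within a diet these comparisons share their 5-month libraries and so their error. With lane as a factor the calls of Fos and Olfml3 were lost at 15 and 18 months in CD and at 15 months under MR. The mean Fos level was 6.63 ± 1.5 FPKM (SD, n = 7) in 5M-MR, 2.75 ± 0.262 (n = 8) in 15M-MR and 3 ± 1.08 (n = 7) in 18M-MR, and that of Olfml3 4.15 ± 0.624, 9.61 ± 1.5 and 7.3 ± 2.48. The mitochondrially encoded subunits had 0 members listed under their symbols and were not analysed here.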
